A study of Homo sapiens with 12 samples.

How the data were processed

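H1299 cells in DMEM with 10% FCS were treated for 6 h and collected at 12 h or 24 h, per the labels. RNA was purified on RNeasy mini columns with DNase I, and biotin-labelled cRNA was made with the Ambion MessageAmp kit, per the labels' protocols. The labels gave 12 arrays in 6 groups, 3 treatments at 2 times with 2 arrays each, and every array was used. Replicate numbers within a group are only names, given in the order of the accessions. The chip or slide of each array is not given in the sources used here.

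The deposited non-normalized table holds the raw intensity of 48701 probes per array, read with BeadStudio according to the submitters' processing notes, which give no version. Beside each intensity, the same deposited table holds a detection p-value of the probe on that array, and the step size of these p-values gives between 1329 and 1343 negative control probes. The authors' normalized intensities in the series matrix are on the linear scale with nearly the same median on all arrays (65.6 to 65.8), and their normalization method is not given in the sources used here. The authors' deposited table of changes of at least 1.6-fold holds a signed score, the fold of the mean of 2 treated arrays, negative for a fall. Its values were compared with ratios of the group means in the series matrix.

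Raw intensities were corrected for background with the detection p-values, given an offset of 16, quantile normalized and taken to log2 with neqc of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on both arrays of at least 1 group were kept, 19631 of them or 40.3%. Of all probes, 23687 had 1 gene, 35 several and 24979 none by the platform annotation, and 23651 gene identifiers matched the reference gene table while 71 did not. The 5588 kept probes without 1 named gene were left out, and the probe with the highest mean stood for each gene, which left 12117 genes. The median SD between replicates was between 0.05 and 0.08 log2 and replicate arrays correlated at 0.997 to 0.998. Where a gene was below detection on all arrays of a group, only a lower bound of the fold is given in comparisons of 2 groups, computed as the mean of the brighter group minus, for each array of the dimmer group, the higher of the dimmest detected probe and the probe's own value.

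The design, the gene lists, the rule for naming genes and the alternatives were fixed from the labels before the data were examined. The 6 group means were fitted over all 12 arrays with limma, with 6 residual and 5.30 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg at 0.05 within each comparison. The comparisons were lipofection and PTD-DRBD each against control and against each other at both times, the change of each effect from 12 h to 24 h, and the 24 h against the 12 h control. GAPDH is named in every comparison. In each comparison with control, genes were named from the 10 largest rises and 10 largest falls that passed and whose arrays did not overlap, between the routes from the 5 and 5 largest, for changes with time from the 5 largest, and in each list from the 4 members with the largest change that passed. Clone and hypothetical gene names were passed over, 1 with PTD-DRBD at 24 h and 2 between the routes at 24 h, and from the authors' table only genes these rules already name were eligible. Genes changed in all 4 comparisons with control were picked out after the values were seen.

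Gene lists were tested with camera of limma, with its preset correlation and again with an estimated one, adjusted over 18 lists and 6 comparisons. The lists were interferon-stimulated genes, NF-kappaB inflammatory genes, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, ATF4 stress response, endoplasmic reticulum chaperones, heat shock, NRF2 oxidative stress, p53 targets, glycolysis without GAPDH, hypoxia, DNA replication, G2 and mitosis, immediate early genes, lysosome, RNA interference machinery, reference genes and markers of other cell types. List tests for the changes with time, adjusted as their own family, were added after the data were seen. So were the gene classes of small noncoding RNAs and replication-dependent histones, the axis of replicate differences at 12 h as a covariate, the correction of each array for its trend on gene length, and a fit without the second array of both treated groups at 24 h. The axis was the leading singular vector of the replicate differences at 12 h, which held 46.1% of their sum of squares.

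The alternatives fixed in advance were quantile normalization without background correction, the authors' normalized values, cyclic loess, no detection filter, detection on all 12 arrays, every probe, only the arrays of the groups compared, an intensity trend with robust moderation, a fold of 1.6 with or without the test, and each array left out in turn. Leaving out an array leaves its group with a lone array, which is then assumed to vary like the other groups. The mean of that group is then less precise by construction, so calls can be lost without a change of effect. Fitting the chip as a block could not be run. The overlap of calls between the routes was set beside 100 draws of unchanged groups simulated against shared controls.

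The scripts were tested on simulated data in which 200 of 12117 genes were changed, with 20 draws. They recovered 21.3% of genes changed 1.25-fold, 96.5% at 1.6-fold, 99.8% at 2-fold and 100% at 4-fold, and 4.60% of calls were false. A shifted list of 20 members was called in 20 of 20 draws and an unshifted one in 0. The simulated noise was independent between genes, unlike the replicate differences of the real arrays, so these rates need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.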

Results

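H1299 is a human non-small cell lung carcinoma line that lacks p53. Its cells were treated for 6 h with phosphate-buffered saline (control), with an siRNA against GAPDH carried by PTD-DRBD, or with GAPDH siRNA given by lipofection, and RNA was collected at 12 h or 24 h. PTD-DRBD is a fusion of a peptide transduction domain, which crosses cell membranes, to a double-stranded RNA binding domain, which binds the siRNA. Labelled cRNA was read on 12 Illumina BeadChips of 48701 probes, 2 arrays in each of the 6 groups of treatment and time. Between 17990 and 19097 probes were detected per array, and the median raw signal lay between 61.3 and 73.1. The comparisons address how far each route of delivery lowered the target and which other genes changed with it. Changes are given as log2 fold changes on background-corrected and normalized intensities, with the standard error (SE) and the limma adjusted p over 12117 genes, and n = 2 arrays per group throughout. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays against 2, an exact permutation test cannot go below p = 0.333, and the arrays of any gene fail to overlap by chance in 33.3% of cases, so their number limits the precision.

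GAPDH, the target, was at 9.77% of its 12 h control level after PTD-DRBD delivery, a log2 fold change of −3.36 (SE 0.08, limma adjusted p = 9.85e-10, 10.2-fold lower). Lipofection left it at 41.6% of control at 12 h (log2 −1.26, SE 0.08, limma adjusted p = 5.56e-06). At 24 h the level was 14.0% of control with PTD-DRBD (log2 −2.84, limma adjusted p = 6.39e-09, 7.16-fold lower) and 51.3% with lipofection (log2 −0.96, limma adjusted p = 3.11e-05). Raw signals of this probe averaged 35038 ± 1323 (SD, n = 2) in the 12 h control, 3379 ± 26.7 with PTD-DRBD and 13730 ± 72.8 with lipofection. At 24 h they averaged 35533 ± 2300 in the control, 4740 ± 197 with PTD-DRBD and 18642 ± 2229 with lipofection. GAPDH was thus 4.26-fold higher with lipofection than with PTD-DRBD at 12 h (log2 2.09, limma adjusted p = 9.05e-08) and 3.68-fold higher at 24 h (log2 1.88, limma adjusted p = 1.61e-07). The other 2 GAPDH probes gave larger falls, of −4.06 and −4.15 with PTD-DRBD and −1.84 and −2.03 with lipofection at 12 h (SE 0.11), and of −3.47 and −3.65 with PTD-DRBD and −1.40 and −1.46 with lipofection at 24 h. From 12 h to 24 h the effect moved by 0.51 with PTD-DRBD (limma adjusted p = 0.0645) and by 0.30 with lipofection (limma adjusted p = 0.116), neither of which passed.

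**Figure D1:**
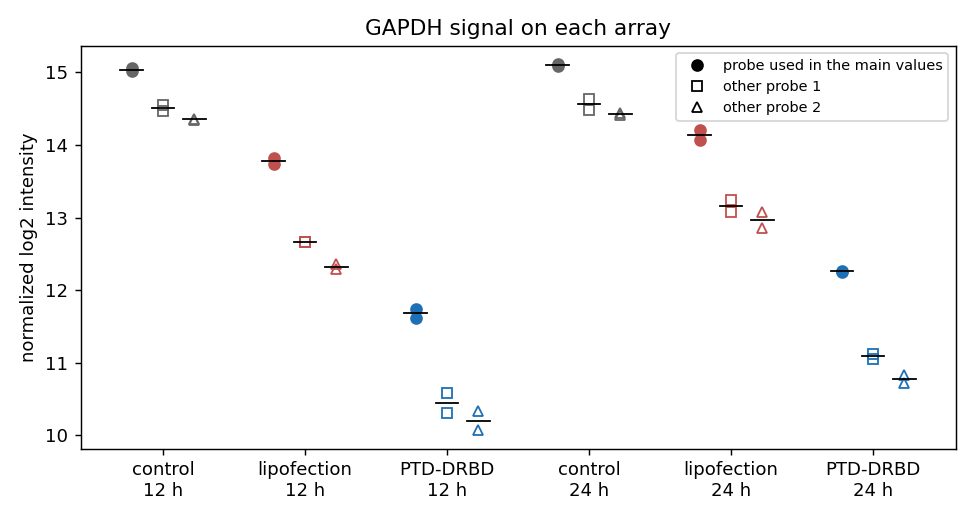
Normalized log2 intensity of the 3 GAPDH probes on each of the 12 arrays, grouped by treatment and time, with a black bar at each group mean of 2 arrays. For the probe used for the values in the text (filled circles), the PTD-DRBD arrays lie below the lipofection arrays and both lie below the controls at both times.

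The largest rises with lipofection at 12 h were of single small noncoding RNAs, HMOX1 and AP-1 genes. RN7SK, the 7SK RNA that restrains transcription elongation, rose by 3.07 on the log2 scale (SE 0.17, limma adjusted p = 3.33e-06), RPPH1, the RNA of RNase P, by 2.74 (SE 0.17) and SNORD15B, a small nucleolar RNA, by 2.67 (SE 0.13). HMOX1, the heme oxygenase that breaks down heme under oxidative stress, rose by 2.64 (SE 0.07, limma adjusted p = 5.11e-09). The AP-1 genes FOSB and FOS rose by 2.37 (SE 0.09, detected on 1 of 2 control arrays) and 2.18 (SE 0.29). The histone genes H3C12 and H4C2 also rose, the first by 1.61 (SE 0.10) and the second at least 3.15-fold from below detection in the control. The largest falls were of CCL2, a monocyte-attracting chemokine, at −1.80 (SE 0.16, limma adjusted p = 5.68e-05), AFF3 at −1.53 (SE 0.12), NOL12, a nucleolar protein, at −1.53 (SE 0.12), the kinase gene ALPK2 at −1.43 (SE 0.10) and the receptor gene TNFRSF9 at −1.36 (SE 0.10). In all, 1439 genes passed, 600 higher and 839 lower, of which 178 changed at least 1.6-fold. Fewer passed without 1 control array (638 or 710) or without 1 lipofection array (616 or 516).

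Among gene lists fixed in advance, the 12 h lipofection arrays were highest for the NRF2, cholesterol and ATF4 lists and lowest for the inflammatory list. NRF2-driven oxidative stress genes rose in 13 of 18 measured members with 0 lower (15 and 1 within the list, meaning adjusted over the list alone; camera adjusted p = 4.83e-13). They included GCLM, which makes glutathione, at 1.14 (SE 0.08) and SRXN1 at 1.09 (SE 0.11). SLC7A11, the cystine transporter, belongs to this list and the ATF4 list and rose by 1.20 (SE 0.12, detected on 1 of 2 control arrays). Cholesterol synthesis and uptake genes rose in 13 of 20 with 0 lower (18 and 0 within the list; camera adjusted p = 3.78e-14). They included HMGCS1 at 1.21 (SE 0.08), MSMO1 at 0.99 (SE 0.07) and MVD at 0.95 (SE 0.12). Genes of the ATF4 integrated stress response rose in 15 of 29 with 0 lower (18 and 0 within the list; camera adjusted p = 5.06e-12). They included the transcription factors DDIT3 at 1.6 (SE 0.11) and ATF3 at 1.51 (SE 0.09). Lysosomal genes rose in 10 of 27 with 0 lower (14 and 1 within the list; camera adjusted p = 4.59e-07). They included the sialidase NEU1 at 1.06 (SE 0.10) and the autophagy receptor SQSTM1 at 0.65 (SE 0.10). NF-kappaB-driven inflammatory genes fell in 10 of 17 with 1 higher (10 and 1 within the list; camera adjusted p = 6.23e-06). They included TRAF1 at −1.31 (SE 0.11), CCL20 at −0.98 (SE 0.13) and CXCL8, at least 1.67-fold lower and below detection with lipofection. These 5 lists also passed with an estimated correlation, at adjusted p = 0.0111 for the NRF2, cholesterol and lysosome lists, 0.0157 for the ATF4 list and 0.0167 for the inflammatory list.

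Another 3 lists passed with lipofection at 12 h only with the preset correlation. Genes of G2 and mitosis rose in 9 of 30 with 0 lower (12 and 0 within the list; camera adjusted p = 6.36e-07, but adjusted p = 0.144 with an estimated correlation). They included KIF20A at 0.52 (SE 0.09) and CDC25C at 0.50 (SE 0.07). DNA replication genes fell in 7 of 33 with 0 higher (8 and 0 within the list; camera adjusted p = 0.00631, but adjusted p = 0.564 with an estimated correlation). They included the helicase subunit MCM6 at −0.75 (SE 0.09), CCNE1 at −0.66 (SE 0.11) and MCM10 at −0.63 (SE 0.07). Chaperones and degradation factors of the endoplasmic reticulum were higher in 5 and lower in 1 of 19 (7 and 1 within the list; camera adjusted p = 0.00355, but adjusted p = 0.062 with an estimated correlation). DNAJB9 was at 0.80 (SE 0.08).

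The other 10 lists did not pass camera with lipofection at 12 h. Of 32 measured interferon-stimulated genes, 2 were higher and 7 lower (2 and 7 within the list; camera adjusted p = 0.161). They included IFIT2, induced by interferon, at 0.89 (SE 0.10) and IFIH1, a sensor of double-stranded RNA, at −0.65 (SE 0.08). Fatty acid synthesis genes were higher in 3 and lower in 0 of 19 (4 and 0 within the list; camera adjusted p = 0.0521). ME1 was at 0.77 (SE 0.07). Immediate early genes were higher in 6 and lower in 3 of 22 (7 and 6 within the list; camera adjusted p = 0.383), and their median of −0.03 differed in sign from their mean of 0.23 and from the direction of the test. Glycolysis genes other than GAPDH were higher in 3 and lower in 2 of 20 (3 and 2 within the list; camera adjusted p = 0.15). The glucose transporter SLC2A3 was at 1.04 (SE 0.10). Hypoxia-induced genes were higher in 1 and lower in 2 of 19 (3 and 2 within the list; camera adjusted p = 0.203). ANGPTL4 was at −0.82 (SE 0.11). Among p53 target genes, a control list in this line, 2 of 20 were higher and 1 lower (2 and 1 within the list; camera adjusted p = 0.449). Genes of the RNA interference machinery gave 1 higher and 1 lower of 17 (1 and 1 within the list; camera adjusted p = 0.449), the first being TNRC6A, an Argonaute partner, at 0.50 (SE 0.08). No member passed in either direction, over all genes or within the list, among 18 heat shock genes (camera adjusted p = 0.25), 15 reference genes (camera adjusted p = 0.336) and the 5 measured of 19 markers of leukocytes, erythrocytes, fibroblasts and endothelium (camera adjusted p = 0.318).

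At 24 h after lipofection the small nucleolar RNAs led the rises. SNORD15B was higher by 4.40 (SE 0.13, limma adjusted p = 4.36e-09), SNORD4A by 2.86 (SE 0.12), SNORD21 by 2.32 (SE 0.10) and SNORD38B at least 4.32-fold from below detection in the control. HMOX1 stayed high at 2.97 (SE 0.07, limma adjusted p = 1.37e-09) and RN7SK at 2.86 (SE 0.17). NOL12 at −1.30 (SE 0.12, limma adjusted p = 4.73e-05), the proteoglycan VCAN at −1.25 (SE 0.13), LIN7C at −1.24 (SE 0.18), TMTC2 at −1.17 (SE 0.18) and TWSG1, a modulator of BMP signalling, at −1.10 (SE 0.13) fell most. Of all genes, 2854 passed, 1286 higher and 1568 lower, of which 265 changed at least 1.6-fold. The count was 1555 or 1502 without 1 control array and 1181 without the second lipofection array. Arrays of the treated groups at 24 h lay high on the main axis of the replicate differences at 12 h (0.33 and 1.5 SD for lipofection, 0.71 and 1.46 SD for PTD-DRBD, −0.20 and −0.65 SD for the control). The first PTD-DRBD array at 12 h, at 0.79 SD, lay above the first array of both treated groups at 24 h, and the second lay at −1.57 SD. Without the second array of both treated groups 1166 genes passed, and with the axis as a covariate 1924 did.

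The oxidative stress list was again high with lipofection at 24 h. NRF2-driven genes rose in 12 of 18 with 0 lower (14 and 1 within the list; camera adjusted p = 2.96e-09, adjusted p = 0.0182 with an estimated correlation). They included SRXN1 at 1.29 (SE 0.11), the thioredoxin reductase TXNRD1 at 0.93 (SE 0.08) and the quinone reductase NQO1 at 0.89 (SE 0.07). Lysosomal genes rose in 12 of 27 with 0 lower (13 and 0 within the list; camera adjusted p = 8.07e-06, adjusted p = 0.0157 with an estimated correlation). They included NEU1 at 0.97 (SE 0.10) and SQSTM1 at 0.86 (SE 0.10). Genes of G2 and mitosis fell in 19 of 30 with 0 higher (24 and 0 within the list; camera adjusted p = 6.66e-09, but adjusted p = 0.0977 with an estimated correlation). They included HMMR at −0.71 (SE 0.12), CENPF at −0.67 (SE 0.09) and the mitotic kinase PLK1 at −0.64 (SE 0.11). DNA replication genes fell in 9 of 33 with 0 higher (15 and 0 within the list; camera adjusted p = 1.11e-04, but adjusted p = 0.433 with an estimated correlation). They included CHAF1A at −0.54 (SE 0.09) and POLD1 at −0.49 (SE 0.08). The p53 targets, a control list because this line lacks p53, passed here with the preset correlation, so the call is no sign of p53 activity. They were higher in 5 of 20 with 0 lower (5 and 0 within the list; camera adjusted p = 0.0296, but adjusted p = 0.125 with an estimated correlation). The kinase gene PLK2 was at 0.82 (SE 0.14) and GADD45B at 0.73 (SE 0.11). The p53 call was lost without the first control array (adjusted p = 0.0835) or the first lipofection array (adjusted p = 0.0846), within a range of 0.0107 to 0.0846 over the other settings apart from the estimated correlation.

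Several lists that passed at 12 h did not pass with lipofection at 24 h. ATF4 stress genes were higher in 7 and lower in 4 of 29 (8 and 7 within the list; camera adjusted p = 0.544). DDIT3 was at 1.45 (SE 0.11), GDF15, a stress-induced cytokine, at 0.95 (SE 0.10) and the amino acid transporter SLC7A5 at −0.74 (SE 0.11). Inflammatory genes were higher in 4 and lower in 1 of 17 (4 and 1 within the list; camera adjusted p = 0.383). NFKB2 was at 0.60 (SE 0.09). Cholesterol genes were higher in 1 and lower in 1 of 20 (0 and 0 within the list; camera adjusted p = 0.831), and endoplasmic reticulum chaperones in 2 and 2 of 19 (2 and 2 within the list; camera adjusted p = 0.895). Interferon-stimulated genes were higher in 5 and lower in 4 of 32 (5 and 4 within the list; camera adjusted p = 0.728). IFIT3 was at 0.86 (SE 0.11) and IFIT2 at 0.72 (SE 0.10). Immediate early genes were higher in 6 and lower in 4 of 22 (6 and 4 within the list; camera adjusted p = 0.114), with FOSB at least 2.16-fold higher. Glycolysis genes were higher in 1 and lower in 6 of 20 (4 and 9 within the list; camera adjusted p = 0.114). The fatty acid, hypoxia, RNA interference, heat shock, reference gene and other cell type lists also did not pass (camera adjusted p from 0.312 to 0.843), and the reference genes' median of 0.02 differed in sign from their mean of −0.05 and the test.

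Small noncoding RNAs and replication-dependent histones were examined as gene classes only after their members had appeared among the largest rises. Of 48 small noncoding RNA genes, 25 rose and 1 fell with lipofection at 12 h (median 0.44) and 36 rose at 24 h (median 1.05), both short of passing with an estimated correlation (adjusted p = 0.0641 and 0.0555). Of 49 histone genes, 15 rose and 3 fell at 12 h (median 0.23, adjusted p = 0.221 with an estimated correlation) and 37 rose at 24 h (median 0.61, adjusted p = 0.0714 with an estimated correlation). With PTD-DRBD, 2 noncoding RNAs and 1 histone gene were higher and 0 and 2 lower at 12 h (medians 0.04 and 0.05), and 14 and 8 were higher and 0 and 1 lower at 24 h (medians 0.29 and 0.21, adjusted p = 0.165 and 0.263 with an estimated correlation). Between the routes, lipofection was higher in 26 noncoding RNAs and lower in 2 at 12 h (median 0.48, adjusted p = 0.0714 with an estimated correlation), and higher in 26 and lower in 0 at 24 h (median 0.73, adjusted p = 0.0555 with an estimated correlation). For histones these counts were 17 and 2 at 12 h (median 0.16, adjusted p = 0.221 with an estimated correlation) and 22 and 0 at 24 h (median 0.44, adjusted p = 0.0952 with an estimated correlation). After each array was corrected for its trend on gene length, the lipofection medians of the noncoding class were 0.13 and 0.42 at 12 h and 24 h and those of the histones 0.13 and 0.38, while at 24 h with PTD-DRBD they were 0.06 and 0.06. Over all settings the noncoding class with lipofection ran from 0.13 to 0.53 at 12 h and from 0.42 to 1.15 at 24 h, and the histones from 0.13 to 0.29 and from 0.38 to 0.73. With PTD-DRBD at 12 h the medians changed sign with the array left out, from −0.05 to 0.11 for noncoding RNAs and from −0.03 to 0.11 for histones.

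Against the mean of the 4 control arrays, the small noncoding RNA class had a median of 0.90 and 1.06 on the 2 lipofection arrays at 24 h, 0.14 and 0.31 on the PTD-DRBD arrays, and between −0.08 and 0.08 on the control arrays. The array higher in each treated 24 h pair is also the one that lay higher on the axis of replicate differences.

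**Figure D2:**
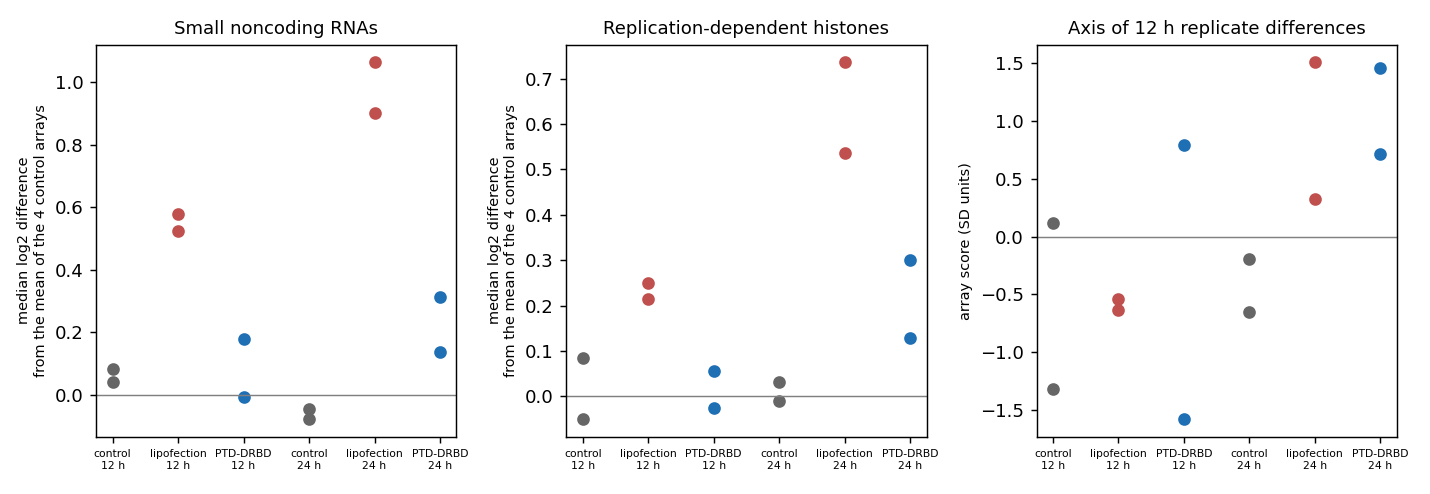
Median log2 difference of each array from the mean of the 4 control arrays for the small noncoding RNA and histone classes (left and middle), and each array's score, in SD over the 12 arrays, on the axis of the 12 h replicate differences (right); each point is 1 array. The lipofection arrays at 24 h lie highest for both classes, at 0.90 and 1.06 for noncoding RNAs and 0.54 and 0.74 for histones.

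With PTD-DRBD at 12 h, apart from GAPDH, the largest rises were of AMHR2, the receptor of anti-Müllerian hormone, at 2.42 (SE 0.10, limma adjusted p = 3.74e-07, detected on 1 of 2 control arrays) and of genes below detection in the control. TPPP3 rose at least 2.83-fold, the protease inhibitor SPINT2 at least 2.31-fold, the hair keratin KRT34 at least 2.2-fold and the matrix protease MMP10 at least 2.16-fold. FOSB rose by 1.21 (SE 0.09, detected on 1 of 2 control arrays), EGR1, an immediate early transcription factor, by 1.01 (SE 0.08) and HMOX1 by 0.61 (SE 0.07). NOL12 fell most after GAPDH, at −1.65 (SE 0.12, limma adjusted p = 3.33e-05), followed by GPR137B at −1.17 (SE 0.10), ZNF467 at −1.15 (SE 0.08), the Wnt receptor FZD7 at −1.11 (SE 0.14) and BHLHE40 at −1.06 (SE 0.10). In this comparison 955 genes passed, 414 higher and 541 lower, and 85 changed at least 1.6-fold. The count was 317 or 314 without 1 control array and 309 or 437 without 1 PTD-DRBD array.

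The clearest list with PTD-DRBD at 12 h was the ATF4 stress response, which rose in 19 of 29 members with 0 lower (23 and 0 within the list; camera adjusted p = 5.19e-18, adjusted p = 0.0111 with an estimated correlation). Its members included ASNS, asparagine synthetase, by 0.98 (SE 0.07), the glycine transporter SLC6A9 by 0.98 (SE 0.10) and DDIT3 by 0.87 (SE 0.11). Cholesterol genes were higher in 6 of 20 with 0 lower (8 and 2 within the list; camera adjusted p = 0.00379, but adjusted p = 0.0877 with an estimated correlation). HMGCS1 was at 0.77 (SE 0.08). Interferon-stimulated genes were lower in 4 of 32 with 0 higher (8 and 1 within the list; camera adjusted p = 7.19e-04, but adjusted p = 0.106 with an estimated correlation). IFIH1 was at −0.57 (SE 0.08). Inflammatory genes were lower in 4 of 17 with 0 higher (7 and 1 within the list; camera adjusted p = 0.018, but adjusted p = 0.106 with an estimated correlation). The inflammatory call was lost without the first control array (adjusted p = 0.0653) and with no detection filter (adjusted p = 0.0525), in a range of 0.00886 to 0.0653 over the other settings. NRF2 genes were higher in 3 and lower in 2 of 18 (5 and 2 within the list; camera adjusted p = 0.625). The transporter ABCC3 was at −0.80 (SE 0.08). Immediate early genes were higher in 5 and lower in 1 of 22 (5 and 3 within the list; camera adjusted p = 0.544). Lysosomal genes gave 1 in each direction of 27 (1 and 1 within the list; camera adjusted p = 0.919), and genes of G2 and mitosis 0 higher and 1 lower of 30 (0 and 1 within the list; camera adjusted p = 0.19). The other lists did not pass (camera adjusted p from 0.337 to 0.985), and the median, mean and test of the glycolysis, lysosome and reference gene lists, all near 0, did not share 1 sign.

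At 24 h with PTD-DRBD the largest changes were falls. NOL12 was at −1.55 (SE 0.12), GPR137B at −1.51 (SE 0.10, limma adjusted p = 2.83e-05), LRATD2 at −1.24 (SE 0.10), TMTC2 at −1.18 (SE 0.18), GPR176 at −1.15 (SE 0.17) and TWSG1 at −1.13 (SE 0.13). AMHR2 was at least 1.77-fold higher than in the control, where it was below detection, DDIT3 rose by 0.98 (SE 0.11), LETM2 by 0.80 (SE 0.12) and ANKRD1, a cofactor induced by stretch and injury, by 0.74 (SE 0.11). A total of 1699 genes passed, 711 higher and 988 lower, of which 122 changed at least 1.6-fold. The count fell to 179 without the second PTD-DRBD array, to 466 or 355 without 1 control array, to 221 without the second array of both treated groups, and to 374 with the axis of 12 h replicate differences as a covariate. Across genes, that axis had a correlation of 0.43 with this comparison and 0.32 with the lipofection comparison at 24 h, against 0.07 and 0.00261 with those at 12 h. Genes are not independent replicates, so these correlations carry no p-value.

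Cholesterol genes were lower with PTD-DRBD at 24 h, in 7 of 20 with 0 higher (10 and 0 within the list; camera adjusted p = 3.1e-04, adjusted p = 0.0472 with an estimated correlation). The sterol carrier STARD4 was at −0.72 (SE 0.14) and IDI1, of isoprenoid synthesis, at −0.45 (SE 0.08), but neither passed without the second control array (STARD4 −0.66, IDI1 −0.37) or the second PTD-DRBD array (STARD4 −0.56, IDI1 −0.41). Hypoxia-induced genes were lower than in the 24 h control in 6 of 19 with 0 higher (6 and 0 within the list, camera adjusted p = 0.00265, but adjusted p = 0.554 with an estimated correlation). ANGPTL4 was at −0.76 (SE 0.11) and INSIG2, which retains SREBP in the endoplasmic reticulum, at −0.61 (SE 0.09). The median of the hypoxia list was −0.17 against a control in which it had risen by 0.40 from 12 h to 24 h. Glycolysis genes were lower in 6 of 20 with 0 higher (8 and 2 within the list; camera adjusted p = 0.0227, but adjusted p = 0.554 with an estimated correlation). The glucose transporter SLC2A1 was at −0.53 (SE 0.08). The glycolysis call ended without the second control array (adjusted p = 0.165) or the first PTD-DRBD array (adjusted p = 0.0616), in a range of 0.00493 to 0.165. On the axis of 12 h replicate differences, on which the PTD-DRBD arrays at 24 h scored 0.71 and 1.46 SD, the hypoxia, glycolysis and fatty acid lists had the lowest median loadings of the 18 lists (−0.480, −0.477 and −0.521 in units of 0.01). The calls of the hypoxia and glycolysis lists held with that axis as a covariate. Fatty acid synthesis genes were lower in 4 of 19 with 0 higher (5 and 0 within the list; camera adjusted p = 0.0206, but adjusted p = 0.495 with an estimated correlation), a call that ended without the second PTD-DRBD array (adjusted p = 0.0611), without the second array of both treated groups (adjusted p = 0.062) and with the axis covariate (adjusted p = 0.117), in a range of 0.00541 to 0.117. ATF4 genes were higher in 5 and lower in 1 of 29 (6 and 1 within the list; camera adjusted p = 0.0424, but adjusted p = 0.438 with an estimated correlation). ASNS was at 0.53 (SE 0.07).

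The ATF4 call with PTD-DRBD at 24 h ended in 8 of 21 settings apart from the estimated correlation, and over all 21 the adjusted p ran from 0.00818 to 0.176. It was lost without the first or second 12 h control array (adjusted p = 0.0528 and 0.0547), the first or second 12 h PTD-DRBD array (0.0555 and 0.054), the second 24 h control array (0.0989) and the first 24 h PTD-DRBD array (0.176), as well as over genes detected on all 12 arrays (0.0679) and after a correction for gene length (0.071). DNA replication genes were lower in 1 of 33 with 0 higher (1 and 0 within the list; camera adjusted p = 0.0824). Genes of the NRF2 list were higher in 2 and lower in 2 of 18 (3 and 4 within the list; camera adjusted p = 0.831) and lysosomal genes likewise in 2 and 2 of 27 (3 and 2 within the list; camera adjusted p = 0.544). The other lists did not pass with PTD-DRBD at 24 h (camera adjusted p from 0.356 to 0.895).

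**Figure D3:**
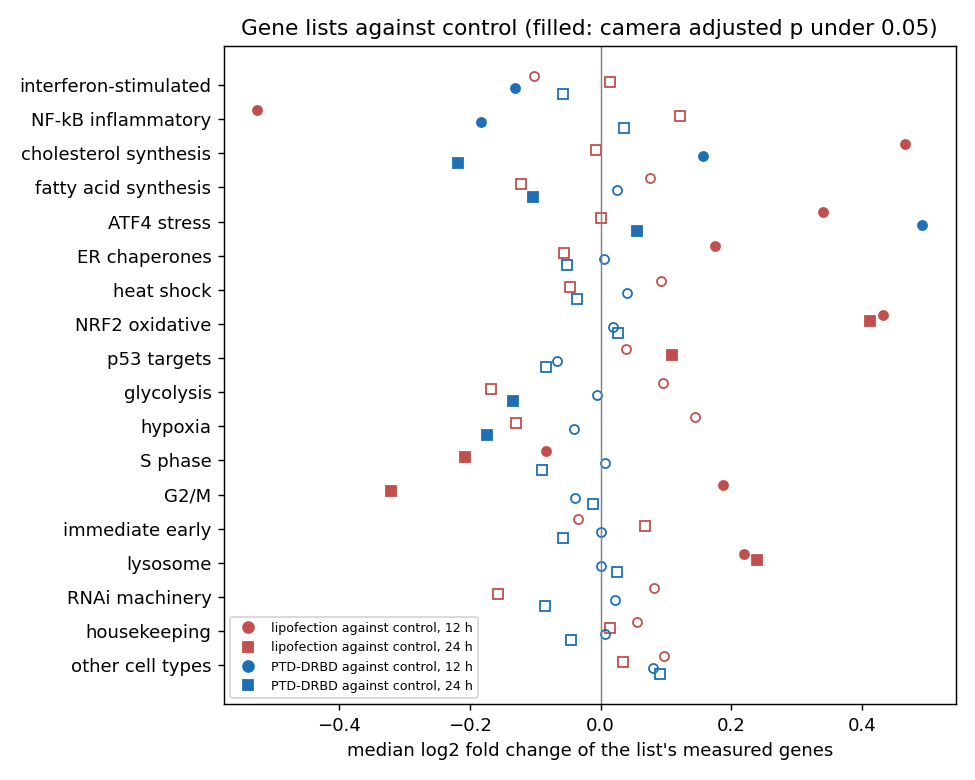
Median log2 fold change against control of the measured genes of each of the 18 lists, for lipofection (red) and PTD-DRBD (blue) at 12 h (circles) and 24 h (squares); filled symbols have a camera adjusted p under 0.05. The NRF2 list lies at 0.43 and 0.41 with lipofection and at 0.02 and 0.03 with PTD-DRBD.

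Compared directly at 12 h, lipofection was above PTD-DRBD for RN7SK by 2.52 (SE 0.17), RPPH1 by 2.40 (SE 0.17), SNORD15B by 2.33 (SE 0.13) and HMOX1 by 2.03 (SE 0.07, limma adjusted p = 9.05e-08). It was below for AMHR2, at least 5.3-fold, TPPP3, at least 2.84-fold, TAFA3, a secreted chemokine-like protein, at −1.43 (SE 0.10) and SPINT2 at −1.31 (SE 0.10, detected on 1 of 2 lipofection arrays). NRF2 genes were higher in 14 of 18 with 0 lower (15 and 0 within the list; camera adjusted p = 1.32e-13). They included NQO1 at 0.99 (SE 0.07). Cholesterol genes were higher in 10 of 20 with 0 lower (13 and 0 within the list; camera adjusted p = 7.18e-09). They included INSIG1 at 1.09 (SE 0.09) and IDI1 at 0.71 (SE 0.08). Lysosomal genes were higher in 10 of 27 with 0 lower (15 and 0 within the list; camera adjusted p = 1.15e-07). They included SQSTM1 at 0.81 (SE 0.10). These 3 lists each passed at adjusted p = 0.0111 with an estimated correlation. Genes of G2 and mitosis were higher in 10 of 30 with 0 lower (18 and 0 within the list; camera adjusted p = 6.57e-09, but adjusted p = 0.0977 with an estimated correlation). KIF20A was at 0.72 (SE 0.09). DNA replication genes were lower in 9 of 33 with 0 higher (11 and 3 within the list; camera adjusted p = 0.00854, but adjusted p = 0.578 with an estimated correlation). MCM6 was at −0.74 (SE 0.09).

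Inflammatory genes were lower with lipofection than with PTD-DRBD at 12 h in 8 of 17 with 1 higher (8 and 2 within the list; camera adjusted p = 0.00315, but adjusted p = 0.062 with an estimated correlation). They included CCL2 at −1.12 (SE 0.16), the neutrophil chemokine CXCL2 at −1.06 (SE 0.10) and CXCL8, at least 1.61-fold lower. Chaperones of the endoplasmic reticulum were higher in 2 of 19 with 0 lower (4 and 0 within the list; camera adjusted p = 0.0102, but adjusted p = 0.0906 with an estimated correlation). DNAJB9 was at 0.94 (SE 0.08). Interferon-stimulated genes went both ways, 5 higher and 5 lower of 32 (7 and 5 within the list; camera adjusted p = 0.383). IFIT1 was at 0.98 (SE 0.17) and IFIT2 at 0.96 (SE 0.10). ATF4 genes were higher in 4 and lower in 7 of 29 (4 and 8 within the list; camera adjusted p = 0.192). ATF3 was at 0.87 (SE 0.09) and SLC6A9 at −0.78 (SE 0.10). The other 9 lists did not pass (camera adjusted p from 0.0578 to 0.984), and the heat shock list's median of −0.02 differed in sign from its mean of 0.01 and the test. Between the routes 1793 genes passed at 12 h, 789 higher and 1004 lower with lipofection, of which 196 differed at least 1.6-fold. The count was 876 or 1115 without 1 PTD-DRBD array and 738 or 697 without 1 lipofection array.

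At 24 h the difference between the routes was again led by SNORD15B at 3.69 (SE 0.13, limma adjusted p = 3.11e-08), HMOX1 at 2.62 (SE 0.07), SNORD4A at 2.54 (SE 0.12) and SNORD38B, at least 4.21-fold higher with lipofection. SPINT2 at −1.15 (SE 0.10, detected on 1 of 2 lipofection arrays), SAMD4A at −0.94 (SE 0.08), CAMKV at −0.90 (SE 0.09) and AMHR2, at least 1.73-fold, were lower with lipofection. NRF2 genes were higher in 11 of 18 with 0 lower (12 and 0 within the list; camera adjusted p = 3.78e-14, adjusted p = 0.0111 with an estimated correlation). They included SRXN1 at 1.15 (SE 0.11) and NQO1 at 0.98 (SE 0.07). Lysosomal genes were higher in 7 of 27 with 0 lower (13 and 0 within the list; camera adjusted p = 2.1e-07, adjusted p = 0.0111 with an estimated correlation). The p53 targets, a control list in a line that lacks p53, passed too, so a list call need not reflect the regulator that names it. They were higher in 5 of 20 with 0 lower (8 and 0 within the list; camera adjusted p = 2.26e-05, adjusted p = 0.0182 with an estimated correlation). They included TP53INP1 at 0.67 (SE 0.10), which did not pass without the second array of both treated groups (0.66). Cholesterol genes were higher in 4 of 20 with 0 lower (4 and 0 within the list; camera adjusted p = 1.25e-04, adjusted p = 0.0393 with an estimated correlation). Genes of G2 and mitosis were lower in 11 of 30 with 0 higher (26 and 0 within the list; camera adjusted p = 2.66e-13, but adjusted p = 0.0518 with an estimated correlation). The centromere gene CENPA was at −0.55 (SE 0.08).

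The weaker list calls between the routes at 24 h were each lost when any of several arrays was left out. DNA replication genes were lower in 3 and higher in 1 of 33 (6 and 1 within the list; camera adjusted p = 0.00368, but adjusted p = 0.554 with an estimated correlation), a call lost without the first PTD-DRBD array (adjusted p = 0.137) or the second lipofection array (adjusted p = 0.0969), in a range of 2.2e-04 to 0.137. Immediate early genes were higher in 6 and lower in 2 of 22 (10 and 2 within the list; camera adjusted p = 0.0106, but adjusted p = 0.554 with an estimated correlation), with FOSB at least 2.11-fold higher; the call was lost without the second PTD-DRBD array (adjusted p = 0.0679) or the first lipofection array (adjusted p = 0.0791), in a range of 0.00308 to 0.0791. Hypoxia-induced genes were higher in 2 of 19 with 0 lower (2 and 0 within the list; camera adjusted p = 0.0424, but adjusted p = 0.634 with an estimated correlation). The hypoxia call was lost without the first 12 h PTD-DRBD array (adjusted p = 0.0511), the first 24 h PTD-DRBD array (0.204), the second 24 h lipofection array (0.262), the second array of both treated groups (0.128) and with the axis covariate (0.0533), in a range of 0.0132 to 0.262. Interferon-stimulated genes were higher in 2 of 32 with 0 lower (2 and 0 within the list; camera adjusted p = 0.454), these being IFIT2 at 1.05 (SE 0.10) and IFIT3 at 0.80 (SE 0.11). The other 9 lists did not pass (camera adjusted p from 0.403 to 0.845), and the fatty acid, glycolysis and RNA interference lists had a median that differed in sign from their mean. In total 1000 genes passed, 568 higher and 432 lower with lipofection, of which 113 differed at least 1.6-fold. The count was 427 or 375 without 1 PTD-DRBD array, 433 or 538 without 1 lipofection array, 142 without the second array of both groups and 1551 with the axis covariate.

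The effect of lipofection changed from 12 h to 24 h for 968 genes, 481 upward and 487 downward. ANKRD1 moved up by 2.01 (SE 0.16, limma adjusted p = 5.3e-04), CCL2 by 1.93 (SE 0.22), SNORD4A by 1.74 (SE 0.17) and SNORD15B by 1.73 (SE 0.18). The G2 and mitosis list moved down in 21 of 30 members with 0 up (27 and 0 within the list; camera adjusted p = 6.19e-17, adjusted p = 0.0411 with an estimated correlation), and the cholesterol list in 10 of 20 with 0 up (15 and 0 within the list; camera adjusted p = 4.57e-11, adjusted p = 0.0117 with an estimated correlation). The inflammatory list moved up in 8 of 17 with 0 down (8 and 1 within the list; camera adjusted p = 2.04e-06, adjusted p = 0.0205 with an estimated correlation). Inflammatory genes fell with time in the control, and that fall is subtracted here, so the move does not show a rise in the lipofected cells. The ATF4 list moved down in 11 and up in 1 of 29 (15 and 1 within the list; camera adjusted p = 5.45e-07, but adjusted p = 0.0531 with an estimated correlation). Weaker moves did not pass with an estimated correlation, down for the fatty acid (adjusted p = 0.327), endoplasmic reticulum (0.119) and glycolysis (0.358) lists and up for interferon-stimulated genes (0.358). The count of genes was 437 or 212 without 1 of the 12 h control arrays, 226 or 177 without 1 of the 12 h lipofection arrays, 310 or 292 without 1 of the 24 h control arrays and 257 without the second 24 h lipofection array.

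With PTD-DRBD, 44 genes changed their effect with time, 15 upward and 29 downward. TPPP3, KRT34 and AMHR2 were among those that moved down, but no size or rank is given here because groups behind these changes were below detection. At 24 h these were the control and PTD-DRBD groups for TPPP3, the PTD-DRBD group for KRT34 and the control for AMHR2, and at 12 h the control for TPPP3 and KRT34. The ATF4 list moved down in 1 of 29 with 0 up (17 and 0 within the list; camera adjusted p = 4.57e-11, adjusted p = 0.0215 with an estimated correlation) and the cholesterol list in 2 of 20 with 0 up (10 and 0 within the list; camera adjusted p = 7.98e-08, adjusted p = 0.0205 with an estimated correlation). The inflammatory (adjusted p = 0.087), interferon (0.263), fatty acid (0.362) and glycolysis (0.383) lists did not pass with an estimated correlation. The count of 44 was 18 or 12 without 1 of the 12 h control arrays, 17 without the second 12 h PTD-DRBD array, 23 without either 12 h lipofection array, 16 or 12 without 1 of the 24 h control arrays, and 83 or 10 without the first or second 24 h PTD-DRBD array.

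Many genes passed in the same direction with both routes. At 12 h, 113 genes were higher and 216 lower in both comparisons with control, and 32 went opposite ways, against 20.5, 37.5 and 55.5 for independent lists of these sizes. At 24 h, 348 were higher, 602 lower and 15 opposite, against 75.5, 128 and 197. Unchanged groups simulated against shared controls gave a median of 0 genes called in both over 100 draws, which follows because no gene was changed. Lists of the observed sizes taken from the top of the simulated ranks shared a median of 158 higher and 154.5 lower genes at 12 h and 354 of each at 24 h. The observed 113 and 348 higher genes did not exceed these medians. Top ranks of a simulation without changed genes hold only noise, so this does not decide whether shared controls gave the excess. In pairs of comparisons that share no array, PTD-DRBD at 12 h and lipofection at 24 h had 136 genes higher in both. Independent lists gave 43.9, and 66 genes were opposite against 111. Lipofection at 12 h and PTD-DRBD at 24 h had 64 higher against 35.2, and 112 opposite against 98.2. The 216 and 602 lower genes exceeded the highest draws, 179 and 400. Across genes, which are not independent replicates, the fold changes of both routes correlated at 0.40 at 12 h and 0.65 at 24 h, against 0.50 simulated at either time, with a covariance of 0.0201 and 0.0444 against 0.00584 simulated. Splitting the 2 control arrays of each time would leave each route with a lone control array and was not done. Part of the excess of lower genes may therefore also come from the shared controls. In all 4 comparisons with control 88 genes were lower and 24 higher, and 6 were lower by at least 1.6-fold in each, singled out after their values were seen. They were GAPDH, NOL12 (from −1.65 to −1.30), CLDN1, a tight junction protein (from −1.20 to −0.73), TGFBI, an extracellular matrix protein (from −0.98 to −0.70), TMTC2 (from −1.18 to −0.72) and PAQR8 (from −0.91 to −0.70). DDIT3 was the 1 gene at least 1.6-fold higher in all 4. Of the genes changed in the same direction, 329 at 12 h became 107 or 122 without 1 control array, 138 or 182 without 1 PTD-DRBD array and 154 or 133 without 1 lipofection array. The 950 at 24 h became 288 or 238 without 1 control array, 151 without the second PTD-DRBD array, 502 without the second lipofection array, 138 without both of these, and 244 with the axis covariate.

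The authors' deposited table of probes changed at least 1.6-fold listed 45 probes for PTD-DRBD and 105 for lipofection at 12 h, and 55 and 179 at 24 h. Of those in the authors' deposited table, 18 were higher and 27 lower with PTD-DRBD at 12 h, 57 and 48 with lipofection at 12 h, 10 and 45 with PTD-DRBD at 24 h, and 111 and 68 with lipofection at 24 h. Each listed value lay within 10% of the ratio of group means in the authors' normalized values. Of the probes in the authors' deposited table, 45, 105, 55 and 179 passed the detection filter and 45, 104, 54 and 179 passed limma in the same direction here when every probe was tested.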

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

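The axis of replicate differences, the gene classes, the list tests for changes with time and the rule that joins a test value and its range into a verdict were chosen after the results were seen, as was the measurement error that now gives the range of the uniform-rise test in place of a resampling of its members (0.296 to 1.04). Predictions with their bounds were written before their tests for measured snoRNA hosts, shared controls, proportion to GAPDH, intensity, all second arrays and gene length, and after them for the others. Apart from the uniform-rise test, the ranges below come from resampling genes. They leave out the spread between arrays, and genes are not independent replicates. The ranges may thus be too narrow, which limits the verdicts drawn with them.

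Small noncoding RNA and histone genes had medians of 1.05 and 0.61 with lipofection at 24 h, although neither class passed with an estimated correlation (adjusted p = 0.0555 and 0.0714). For the noncoding class, the values argue against the normalization of dim probes. Its lowest median with lipofection over 3 other normalizations and both times was 0.295 (range 0.2 to 0.454). That value belongs to 12 h, where the main median was 0.44. For 25 of 41 snoRNAs, which lie in 13 hosts, the host mRNAs moved by 0.0577 of the snoRNA median (range −0.000939 to 0.107). This argues against a matching rise of host mRNA for these 25. The level of an mRNA does not measure its transcription, so host gene transcription itself stays open. For 16 snoRNAs no host was measured, SNORA7B among them because no host is listed for it, so nothing is decided for those or for all snoRNAs together, and a cause tied to length stays open too, since the gene-length correction, which by construction also takes signal from classes of short genes, left 0.42 and 0.38. Better recovery of short RNAs stays open, with a histone median against PTD-DRBD of 0.16 (0.07 to 0.27) at 12 h and 0.44 at 24 h, on either side of the bound of 0.2. An equal rise of all RNA without poly(A) tails is argued against by the 17 members above the median level, a set widened to both classes after its first result. Their changes ran from −0.03 (H4C3) to 1.51 (H2AC18), with an interquartile range of 0.77 (0.58 to 1.00 by measurement error). An equal rise simulated with measurement error alone gave an upper limit of 0.236. With members resampled instead, the range of 0.296 to 1.04 reached below the bound set for an equal rise and would decide nothing. The verdict thus rests on the range chosen after the results were seen, and an unequal rise stays open.

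Genes lower with both routes were more common than genes of opposite direction. In the 2 pairs of comparisons that share no array the excess was 2.42 (range 2.01 to 3.07) and 5.28 times that of opposite genes, which argues against the shared controls as the whole cause. For proportion to GAPDH, 540 genes lower with PTD-DRBD at 12 h were taken, whatever their change with lipofection. Their median effects at 24 h were −0.208 with lipofection and −0.249 with PTD-DRBD, both against the same control arrays. The ratio of 0.836 (range 0.717 to 0.964), against 0.339 for GAPDH, argues against a strict proportion to the loss of GAPDH. The range reaches below the bound of 0.8 set for that. An effect of the siRNA sequence beyond its target and an effect of handling both stay open, because no group received a carrier alone or another siRNA.

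Differences between replicates were correlated across genes for several groups, at 0.32 between the treated groups at 24 h, −0.40 between PTD-DRBD at 12 h and lipofection at 24 h, and 0.20 and 0.23 between the 12 h control and the treated groups at 24 h, with signs that are arbitrary because replicate numbers are only names. The value of 0.32 was 0.386 after cyclic loess (range 0.370 to 0.402), which argues against an intensity trend. The 24 h control difference correlated at −0.146 (range −0.166 to −0.127) and −0.25 with the treated groups, and since its sign is arbitrary the bound set beforehand decides nothing and a difference that all 24 h arrays share stays open. After the gene-length correction 0.915 of the correlation was left (range 0.898 to 0.932), so gene span, only a proxy for transcript length, was not the whole cause, although the range reaches below the bound of 0.9. RNA quality, amplification or culture may differ between replicates, and without the second treated arrays at 24 h 221 genes passed with PTD-DRBD at 24 h.

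The effect of lipofection changed with time for 968 genes, with ANKRD1 at 2.01, CCL2 at 1.93, SNORD4A at 1.74, SNORD15B at 1.73 and FOS at −1.90. FOS did not pass without the first or second 12 h control array (−1.89 and −1.90), the first or second 12 h lipofection array (−1.79 and −2.00), the first 24 h control array (−1.40), the second 24 h lipofection array (−1.68) or with the axis covariate (−1.86). By list the medians of this change were 0.38 for inflammatory, −0.46 for cholesterol and −0.50 for G2 and mitosis genes. Each of these values subtracts the control's own change with time, which was a fall for inflammatory genes. The effect of PTD-DRBD changed for 44 genes, with ARID5B at −1.21 and PYROXD1 at −1.17 (detected on 1 of 2 PTD-DRBD arrays at 24 h), and list medians of −0.37 for cholesterol and −0.40 for ATF4 genes. The fitted values of TPPP3 (−1.68), KRT34 (−1.35) and AMHR2 (−1.21) rest on groups below detection, so they are no measure of size. ARID5B did not pass without the first or second 12 h control array (−1.19 and −1.23), the second 24 h control array (−1.15) or the second 24 h PTD-DRBD array (−1.08). PYROXD1 did not pass without the second 12 h PTD-DRBD array (−1.12), the second 24 h control array (−1.09) or the second 24 h PTD-DRBD array (−1.17).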

How the results depend on the processing

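None of the 404 named gene values and none of the list calls changed direction in the settings run for them. Genes not named were not followed, and the lists were not run over every probe or with only the arrays of the groups compared. The class medians with PTD-DRBD at 12 h, which did not pass, ran from −0.05 to 0.11 for small noncoding RNAs and from −0.03 to 0.11 for histones. The gene classes, the axis covariate, the gene-length correction and the fit without the second array of both treated groups at 24 h were chosen after the results were seen, and the other settings before. Fitting the chip as a block was not run, because the chip is not given in the sources used here.

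The normalization and moderation moved mainly the changes with time. Without background correction 1533 genes changed their lipofection effect and 284 their PTD-DRBD effect, with the submitters' values 1548 and 273, and with an intensity trend and robust moderation 1534 and 294, against 968 and 44. The PTD-DRBD change was 174 with cyclic loess, 111 over genes detected on all 12 arrays, 21 over every probe and 89 after the gene-length correction. The cause was not tested.

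With only the arrays of the groups compared, PTD-DRBD against control gave 488 genes at 12 h and 889 at 24 h, lipofection against PTD-DRBD at 24 h 209, the PTD-DRBD change 22 and the overlap at 24 h 429. Such a fit has fewer residual degrees of freedom by construction. So does a fit with arrays left out, and its lower count alone does not show that calls depended on those arrays. Requiring 1.6-fold left 178 and 265 genes for lipofection, 85 and 122 for PTD-DRBD, 196 and 113 between the routes, 262 for the lipofection change, 153 for the control over time and 21 and 57 for the overlaps. At 1.6-fold without a test these were 179 and 265, 86 and 124, 196 and 113, 325, 155, and 21 and 58, with 148 for the PTD-DRBD change.

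Leaving out the second array of both treated groups at 24 h gave 1166 genes for lipofection, 221 for PTD-DRBD, 142 between the routes at 24 h, 264 and 12 for the changes with time and 138 for the overlap at 24 h. The axis covariate gave 374 for PTD-DRBD at 24 h, 1551 between the routes at 24 h, 633 for the lipofection change, and 496 and 244 for the overlaps. Because the treated 24 h arrays score high on that axis, the covariate can also remove an effect of treatment.

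With each array left out in turn, lipofection against control ran from 516 to 1486 genes at 12 h and from 1181 to 2894 at 24 h, and PTD-DRBD from 309 to 994 and from 179 to 1869. Between the routes the range was 697 to 1851 at 12 h and 375 to 986 at 24 h, for the lipofection change 177 to 1091, for the PTD-DRBD change 10 to 83, for the control over time 399 to 1120, and for the overlaps 107 to 344 and 151 to 1032. GAPDH stayed between −1.30 and −1.22 with lipofection and between −3.42 and −3.29 with PTD-DRBD at 12 h, and between −1.03 and −0.89 and between −2.85 and −2.83 at 24 h. Of 404 named gene values, 237 kept their call in every setting. Of 37 list calls in the 6 comparisons 16 held with an estimated correlation, and of 20 for changes with time 6 did. Signal near background limits dim genes, whose folds the offset of 16 compresses and the background correction alters.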

Other observations

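In the buffer-treated cells, inflammatory genes were lower at 24 h than at 12 h in 10 of 17 members with 0 higher (13 and 0 adjusted over the list alone; median −0.75, camera adjusted p = 7.88e-18, adjusted p = 0.00359 with an estimated correlation). This fall is subtracted in the change with time of the inflammatory list with both routes. Hypoxia-induced genes were higher in 11 and lower in 2 of 19 (13 and 2 adjusted over the list alone, median 0.40, camera adjusted p = 7.41e-07, but adjusted p = 0.236 with an estimated correlation) and glycolysis genes in 10 and 1 of 20 (11 and 1 adjusted over the list alone, median 0.29, camera adjusted p = 1.76e-07, but adjusted p = 0.116 with an estimated correlation). The rise of the glycolysis list is subtracted in its change with time with both routes. Cholesterol genes were higher in 6 of 20 with 0 lower (7 and 0 adjusted over the list alone; median 0.09, camera adjusted p = 0.00762, but adjusted p = 0.116 with an estimated correlation), a rise that is subtracted in the change with time of this list with both routes. DNA replication genes had 1 of 33 higher and 0 lower (0 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 5.35e-04, but adjusted p = 0.362 with an estimated correlation). Immediate early genes were lower in 4 and higher in 1 of 22 (7 and 2 adjusted over the list alone; median −0.14, camera adjusted p = 0.00762, but adjusted p = 0.382 with an estimated correlation), a call lost without the second 24 h control array (adjusted p = 0.0575, in a range of 0.00282 to 0.0575). In all 1055 genes passed, 503 higher and 552 lower at 24 h, and 399 or 541 without 1 of the 12 h control arrays and 457 or 444 without 1 of the 24 h control arrays. Each comparison with control at 24 h therefore has another baseline than at 12 h.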
